A study of Mus musculus with 10 samples.

How the data were processed

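The series holds 10 arrays of mouse cells of the strain C57BL/6, with 2 arrays each of pericytes, primary OPC and induced OPC at passages 5, 15 and 25, and groups were taken from the sample titles. Per the labels, total RNA was turned into biotin-labelled cRNA. The labels also mention a kit with another round of amplification for RNA of sorted transplanted cells, and do not say whether any of these arrays held such RNA. BeadStudio 3.2, RMA and lumi are named per the submitters' processing notes, with no role stated. Labels do not say whether replicates are separate cultures, so p-values here measure only the spread between these arrays, whose number limits the precision.

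The deposited signal table gives an intensity per probe and array that, per the file headers, is non-normalized, with lowest values above 0 and medians that differ between arrays. Beside each signal stands the deposited detection p-value of the probe, per the file headers, in whole steps that imply 798 negative controls. The authors' value table holds log2 values with the same quantiles in every column (median 3.29 in each of the 10 columns, range 0.519 to 14.4), so these were quantile-normalized before they were deposited. For the PC columns the slope of these values on the log2 signal was 0.983 over 2546 bright probes, which gives the base of the logarithm. No centring of genes was visible and single-channel values have no direction to find, while the background correction behind them stays unknown, and for the other headings the scale could not be set against like-named signals, since those columns did not match. Each table held 25697 probes. A platform annotation gave 23978 of them 1 gene symbol, 0 several and 1719 none, and 23962 were named through a current Entrez identifier.

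Signals were background-corrected from the negative controls implied by the detection p-values (neqc of limma 3.58.1 in R 4.3.3, offset 16), quantile-normalized and put on the log2 scale. A probe was kept with a detection p-value under 0.01 on at least 2 of the 10 arrays, which 14539 probes met, 13680 of them with a symbol. Of 2740 genes with more than 1 such probe, the probe with the highest mean over all arrays was used, which left 9778 genes. The same probes were used in the value table. Both tables were fitted alike with limma (lmFit and eBayes, a mean per group, 5 residual degrees of freedom), and 12 contrasts and an F test over the passages were adjusted by Benjamini-Hochberg over genes. A gene was called at an adjusted p under 0.05, and calls of at least 2-fold were counted beside. All tests were two-sided.

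For a gene below background on all arrays of one side, an at-least fold is given in the signal table: the bright group's mean against the dim group's mean of, per array, the higher of the lowest normalized value of a detected probe and the dim probe's own. Where only some arrays of a group detected a gene, the fitted change is given. The value table has no detection calls, so its changes are log2 differences of the fit and bound nothing.

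In all, 25 gene lists with 566 genes, 362 of them tested, were set against the other genes with limma's camera (preset correlation 0.01, adjusted over lists within a contrast), with an estimated correlation as an alternative. Genes named are the 8 with the largest rises and falls among calls whose arrays did not overlap between the sides, up to 4 members with the largest change of a list described, and 16 markers fixed in advance, leaving out genes of unclear function and a few others not shown here. The contrasts, tests, filters, lists, naming rule and most alternatives were chosen before the data were examined. Giving every comparison from both tables, applying the naming rule to the value table and to genes called in both, naming list members that moved against their list, leaving out arrays of the value table and leaving out the arrays headed iOPC passage 15 or OPC were chosen after seeing the data. Alternatives included other background corrections, scalings, filters, probe rules and variance models, the replicate number as a block and leaving out each array.

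Positions between PC and OPC are projections of each array on the line between the group means over all tested genes. Their chance level, and that of calls shared by comparisons against the same PC arrays, came from 20 simulations of unchanged groups. Of 9778 simulated genes 67, 67 and 66 changed 1.5-, 2- and 4-fold. Of the 2-fold changes the signal table's fit found 98.5% in OPC against PC, 100% in iOPC against PC and 100% in passage 25 against 5, with 9, 11 and 7 false calls in all. Under the spread of the value table it found 20.9%, 49.3% and 31.3%, with 1, 2 and 10 false calls, and for 4-fold changes 87.9%, 90.9% and 83.3%. With so few genes changed, the value table's rates in real comparisons may be higher. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.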

Results

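Messenger RNA was measured on 10 Illumina bead arrays of mouse cells, with 2 arrays in each of 5 groups. The groups were pericytes (PC), contractile cells that wrap small blood vessels; primary oligodendrocyte progenitor cells (OPC), the cells that give rise to the myelinating glia of the brain; and induced OPC made from pericytes (iOPC), sampled after 5, 15 and 25 passages in culture. The OPC samples are titled as progenitors, while their cell type and the design text call them oligodendrocytes. Each array reported 25697 probes, of which between 45.7% and 49.2% were detected, and the mean signal per array ran from 268 to 388, lowest on the arrays headed iOPC passage 25 (299 and 268). The design asks how far the induced cells differ from the cells they came from and from primary OPC, and whether this changes with passage.

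The measurements exist as a table of signals and a table of the authors' normalized values, and the like-named columns of these tables did not hold the same profiles. Over 9403 probes detected on every array, the columns headed PC matched between the tables (mean Pearson r across probes 0.961), but the signal columns headed iOPC passage 15 matched the value columns headed OPC (0.964) and not those headed iOPC passage 15 (0.837). The signal columns headed OPC matched those of no value heading above a mean of 0.865, and like-named columns reached 0.832 for OPC, 0.862 for iOPC passage 5 and 0.849 for passage 25. Sex-linked transcripts followed the same split. The Y-linked genes Eif2s3y, Kdm5d and Uty were detected on both signal arrays headed iOPC passage 15, and the X-inactivation transcript Xist was not. Elsewhere only Uty was detected, on passage 25 replicate 2, near background. In the value table high Y-linked and low Xist values lay in the columns headed OPC. Eif2s3y, below background on the PC arrays, stood at least 29.3-fold above PC in the first and 8.06 log2 units above PC in the second. Replicates correlated at r between 0.997 and 0.998 in the signal table and from 0.908 (iOPC passage 5) to 0.995 (OPC) in the value table. The value columns of passage 5 lay further from each other than, on average, from those of passage 15 (0.928) and passage 25 (0.936). No column was reassigned. Each comparison is therefore given from both tables under the headings as they stand, and the direction of any comparison that rests on a heading other than PC depends on which table carries the right ones. In pairs of values the signal table comes first, as a log2 change or, where one side lay below background on all its arrays, as an at-least fold, and the log2 change in the value table comes second.

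**Figure D1:**
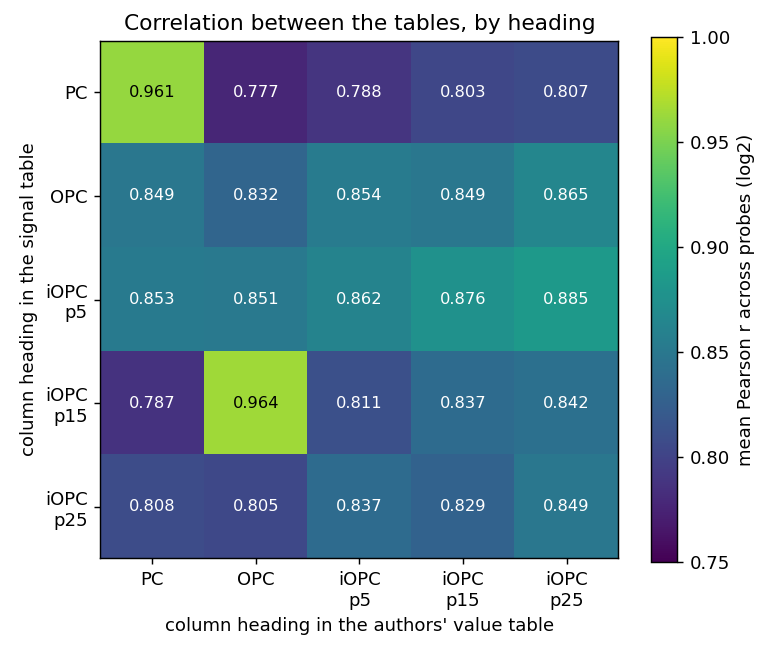
Mean Pearson correlation across 9403 probes between the log2 signal columns (vertical axis, by heading) and the columns of the authors' value table (horizontal axis, by heading), each cell the mean over 2 × 2 column pairs. The PC headings match at 0.961, and the signal heading iOPC p15 matches the value heading OPC at 0.964, while all other cells lie at or below 0.885.

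**Figure D2:**
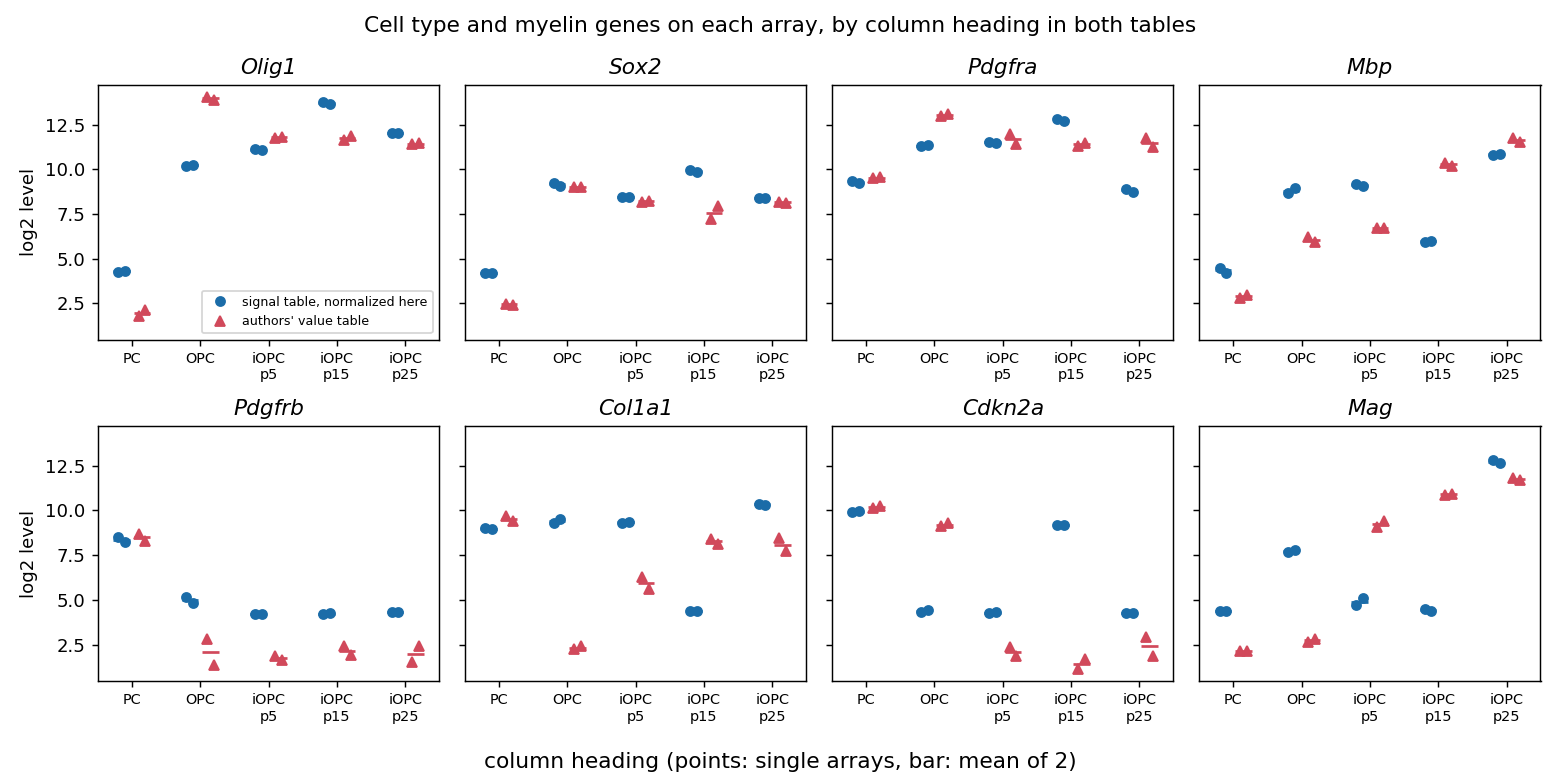
Log2 level of 8 genes on every array (points) with the mean of 2 arrays (bars), by column heading, in the signal table normalized here (blue circles) and in the authors' value table (red triangles). Col1a1 is lowest in the signal columns headed iOPC p15 and in the value columns headed OPC, and among columns not headed PC Cdkn2a is highest in these.

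Compared with pericytes, the iOPC arrays (mean of the 3 passages) carried far more RNA of the oligodendrocyte lineage and far less of matrix, contractile and cell cycle inhibitor genes, in both tables. Olig1, a transcription factor of the oligodendrocyte lineage, rose by at least 161-fold and 9.71. Bcas1, a protein of early myelinating oligodendrocytes, rose by 7.35 and 9.65 and was detected on 1 of the 2 PC arrays. Brevican (Bcan), a proteoglycan of neural matrix, rose by at least 61.5-fold and 10.56. The other top rises were Aldoc, a brain form of the glycolytic enzyme aldolase (7.31 and 6.91), Ttyh1, a membrane protein of neural cells (at least 78.1-fold higher and 8.58), Igfbp2, which binds insulin-like growth factors (at least 70.9-fold higher and 5.82), and Atp1b2, a sodium pump subunit of glia (at least 74.2-fold higher and 6.98). Cldn11, a tight junction protein of myelin, rose by 6.84 in the signal table and fell in the value table (-2.20). Among the falls, the proliferin hormone genes Prl2c3 (at least 554-fold lower and -12.31), Prl2c4 (at least 444-fold lower and -12.41) and Prl2c1 (at least 69.5-fold lower and -8.16) were lower, though their near-identical sequences leave the probe's gene uncertain. Klra4, a receptor gene of a multigene family and open to the same doubt, was lower (at least 166-fold lower and -10.41). Lox, which cross-links collagen, was lower (at least 110-fold lower and -10.06), and so was Nid1, a basement membrane protein (-6.85 and -9.54). Anxa3, an annexin, was lower (-7.53 and -10.57) and was detected on both passage 15 arrays and on no other iOPC array.

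The markers fixed in advance moved the same way in both tables, apart from Gfap. Pdgfra, the growth factor receptor of OPC, rose by 1.76 and 2.00, although at passage 25 it lay below PC in the signal table (-0.46, adjusted p = 0.000454) and above PC in the value table (1.97). The proteoglycan Cspg4 (NG2), present on OPC and on pericytes alike, rose by 3.71 and 4.30. The transcription factors Sox2 (at least 15.7-fold higher and 5.52), Nkx2-2 (at least 3.6-fold higher and 6.10) and Olig2 (at least 1.82-fold higher and 2.75) rose. Nkx2-2 was detected on the 4 signal arrays headed passage 15 and 25, and Olig2 on those headed passage 15 and no other iOPC array. Mbp, a structural protein of myelin, rose by at least 12.9-fold and 6.65 at its brightest probe, while its other passing probes changed by -0.33 and 0.47. The pericyte receptor Pdgfrb fell by at least 11.5-fold and 6.53 and Acta2, smooth muscle actin, by 2.83 and 2.98. Col1a1, a chain of collagen I, fell (-0.96 and -2.10). This fall rested on the arrays headed passage 15, where Col1a1 was not detected: without them the signal table gave a rise of 0.86. Cdkn2a, a cell cycle inhibitor, fell (-4.03 and -8.24) and was detected on the signal arrays headed passage 15 and on no other iOPC array. Gfap, an intermediate filament of astrocytes, rose in the signal table (at least 1.64-fold) and changed by 0.29 in the value table (adjusted p = 0.602). Sox10 and Mki67 had no probe under these symbols and Rgs5 was detected on 0 arrays, so they were not tested.

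8 of the 25 gene lists shifted against the other genes in the same direction in both tables. Unless given, counts adjusted over the list alone were those over all genes. In all, 11 lists passed in each table, and 7 and 0 of these held with an estimated correlation. The OPC identity genes had 22 of 23 tested members higher and 0 lower in the signal table (camera adjusted p = 1.18e-08), and 17 higher and 1 lower in the value table (18 and 1 adjusted over the list alone, camera adjusted p = 6.97e-06). OPC identity genes gave adjusted p = 0.0709 with an estimated correlation in the value table. Examples were Scrg1, a gene of glial precursors (at least 46.7-fold higher and 9.10), and Gpr17, a receptor of differentiating OPC (at least 36.1-fold higher and 10.41). Among 23 tested oligodendrocyte differentiation and myelin genes, 21 rose and 1 fell in the signal table (camera adjusted p = 1.02e-07), and 19 and 1 did so in the value table (camera adjusted p = 3.35e-07). Myelin genes gave adjusted p = 0.058 with an estimated correlation in the value table. Ugt8a, which makes the myelin lipid galactosylceramide, rose by at least 47.1-fold and 7.30, and Gal3st1, which sulfates it, by at least 30.8-fold and 9.01. Of the oligodendroglial transcription factors, 22 of 25 tested members rose and 2 fell in the signal table (camera adjusted p = 2.83e-05), and 14 rose and 3 fell in the value table (camera adjusted p = 0.0287). Transcription factors gave adjusted p = 0.145 with an estimated correlation in the value table. Pou3f1 rose by at least 18-fold and 7.03 and Sox8 by 3.39 and 2.30, while Sox9 (-2.51 and -7.02) and Id4 (-0.71 and -4.39) fell, though at passage 15 the signal table called both higher than PC (0.87 and 0.65).

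The fibroblast and extracellular matrix genes had 2 of 30 tested members higher and 26 lower in the signal table (camera adjusted p = 5.77e-09), and 7 higher and 20 lower in the value table (7 and 21 adjusted over the list alone, camera adjusted p = 0.0001). Extracellular matrix genes gave adjusted p = 0.058 with an estimated correlation in the value table. Fibulin 2 (Fbln2) changed by -5.47 and -11.11, Col1a2, the other chain of collagen I, was lower (at least 26.4-fold lower and -3.80), and S100a4 changed by -4.22 and -5.05. Lum, a collagen-binding proteoglycan, rose (fitted 3.49 and 3.76). It was below background on the PC and passage 15 signal arrays. Among 18 tested pericyte and mural genes, 3 rose and 12 fell in the signal table (camera adjusted p = 0.00223), and 3 and 13 did so in the value table (camera adjusted p = 0.00192). Pericyte and mural genes gave adjusted p = 0.133 and 0.058 with an estimated correlation. The transcription factor Foxc2 fell (-4.34 and -5.17), and the members that rose in both tables were Cspg4, also an OPC gene, and the adhesion molecule Mcam (3.17 and 5.19). Of the smooth muscle contractile genes, 2 of 12 tested members rose and 8 fell in the signal table (3 and 8 adjusted over the list alone, camera adjusted p = 0.00778), and 0 rose and 8 fell in the value table (camera adjusted p = 0.000339). Smooth muscle genes gave adjusted p = 0.0793 and 0.0709 with an estimated correlation. Tropomyosin Tpm2 was lower (at least 25.9-fold lower and -7.76), calponin Cnn2 changed by -3.65 and -3.00 and caldesmon Cald1 by -2.05 and -1.78. The mean of this list in the signal table was -1.44, but -1.20 without both arrays headed passage 15, where it did not pass (adjusted p = 0.058), nor without PC replicate 1 (-1.04, adjusted p = 0.0957). The cell cycle inhibitors and p53 targets had 2 of 18 tested members higher and 14 lower in the signal table (camera adjusted p = 0.000351), and 1 higher and 15 lower in the value table (camera adjusted p = 0.0001). Cell cycle inhibitors and p53 targets gave adjusted p = 0.058 with an estimated correlation in the value table. Cdkn2b fell (-4.51 and -8.32), Perp, a p53 target of cell death, was lower (at least 5.67-fold lower and -4.03), and Pmaip1, another, changed by -2.88 and -3.35. Among 18 tested interferon and antigen presentation genes, 0 rose and 15 fell in the signal table (camera adjusted p = 8.55e-05), and 4 and 12 did so in the value table (camera adjusted p = 0.00891). Interferon genes gave adjusted p = 0.157 with an estimated correlation in the value table. The interferon-induced genes Oasl2 (-3.38 and -5.07), Usp18 (-2.42 and -3.99) and Gbp2 (-1.98 and -3.23) fell.

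Of the astrocyte markers, 15 of 20 tested members rose and 5 fell in the signal table (camera adjusted p = 0.0162), and 6 rose and 7 fell in the value table (6 and 9 adjusted over the list alone, camera adjusted p = 0.834). Astrocyte markers gave adjusted p = 0.0879 with an estimated correlation in the signal table. S100b, a calcium-binding protein of glia, rose by at least 17.1-fold and 7.14 and the glial receptor Gpr37l1 by at least 14.9-fold and 8.01. The neuron markers had 12 of 13 tested members higher and 1 lower in the signal table (camera adjusted p = 0.00106), and 4 higher and 4 lower in the value table (camera adjusted p = 0.887). Map2, a microtubule protein of dendrites, rose by 4.40 and 4.70 and the synaptic vesicle protein Syp by at least 3.76-fold and 4.16. Without both arrays headed passage 15 neither list passed in the signal table, with the astrocyte mean as large as before (log2 change 1.57 after 1.54, adjusted p = 0.0823) and the neuron mean smaller (0.72 after 1.38, adjusted p = 0.199). Cholesterol synthesis genes shifted down in the signal table (3 higher and 12 lower of 18, camera adjusted p = 0.0217, and adjusted p = 0.264 with an estimated correlation) and did not pass in the value table (camera adjusted p = 0.595). Glycolysis and hypoxia genes shifted down in the value table alone (1 higher and 13 lower of 19, camera adjusted p = 0.00178, and adjusted p = 0.058 with an estimated correlation). Immediate early and stress genes did the same (1 higher and 13 lower of 16, camera adjusted p = 0.000145, and adjusted p = 0.058 with an estimated correlation), and cell cycle genes shifted up (16 higher and 1 lower of 28, camera adjusted p = 0.0131, and adjusted p = 0.0709 with an estimated correlation). Without both arrays headed passage 15 the signal table called cell cycle genes down (mean log2 change -0.51, adjusted p = 0.000728). Ribosomal protein genes shifted in neither (camera adjusted p = 0.523 and 0.854).

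Of 9778 genes tested, 4133 were higher and 3333 lower in iOPC than in PC in the signal table (3580 and 3755 with median scaling), and 3223 and 2617 in the value table. At least 2-fold changes among these numbered 1269 up and 1183 down, and 1897 and 1704. Both tables called 2420 genes higher and 2036 lower (1362 and 892 if independent) and 482 in opposite directions (2205). Across genes, which are not independent replicates, the changes correlated at r = 0.801. The matching PC columns build in some agreement. Standard errors of the named genes ran from 0.06 to 0.18 and from 0.11 to 0.70 (2 arrays per group). The largest limma adjusted p among the named genes that passed was 0.00022 and 0.0466.

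**Figure D3:**
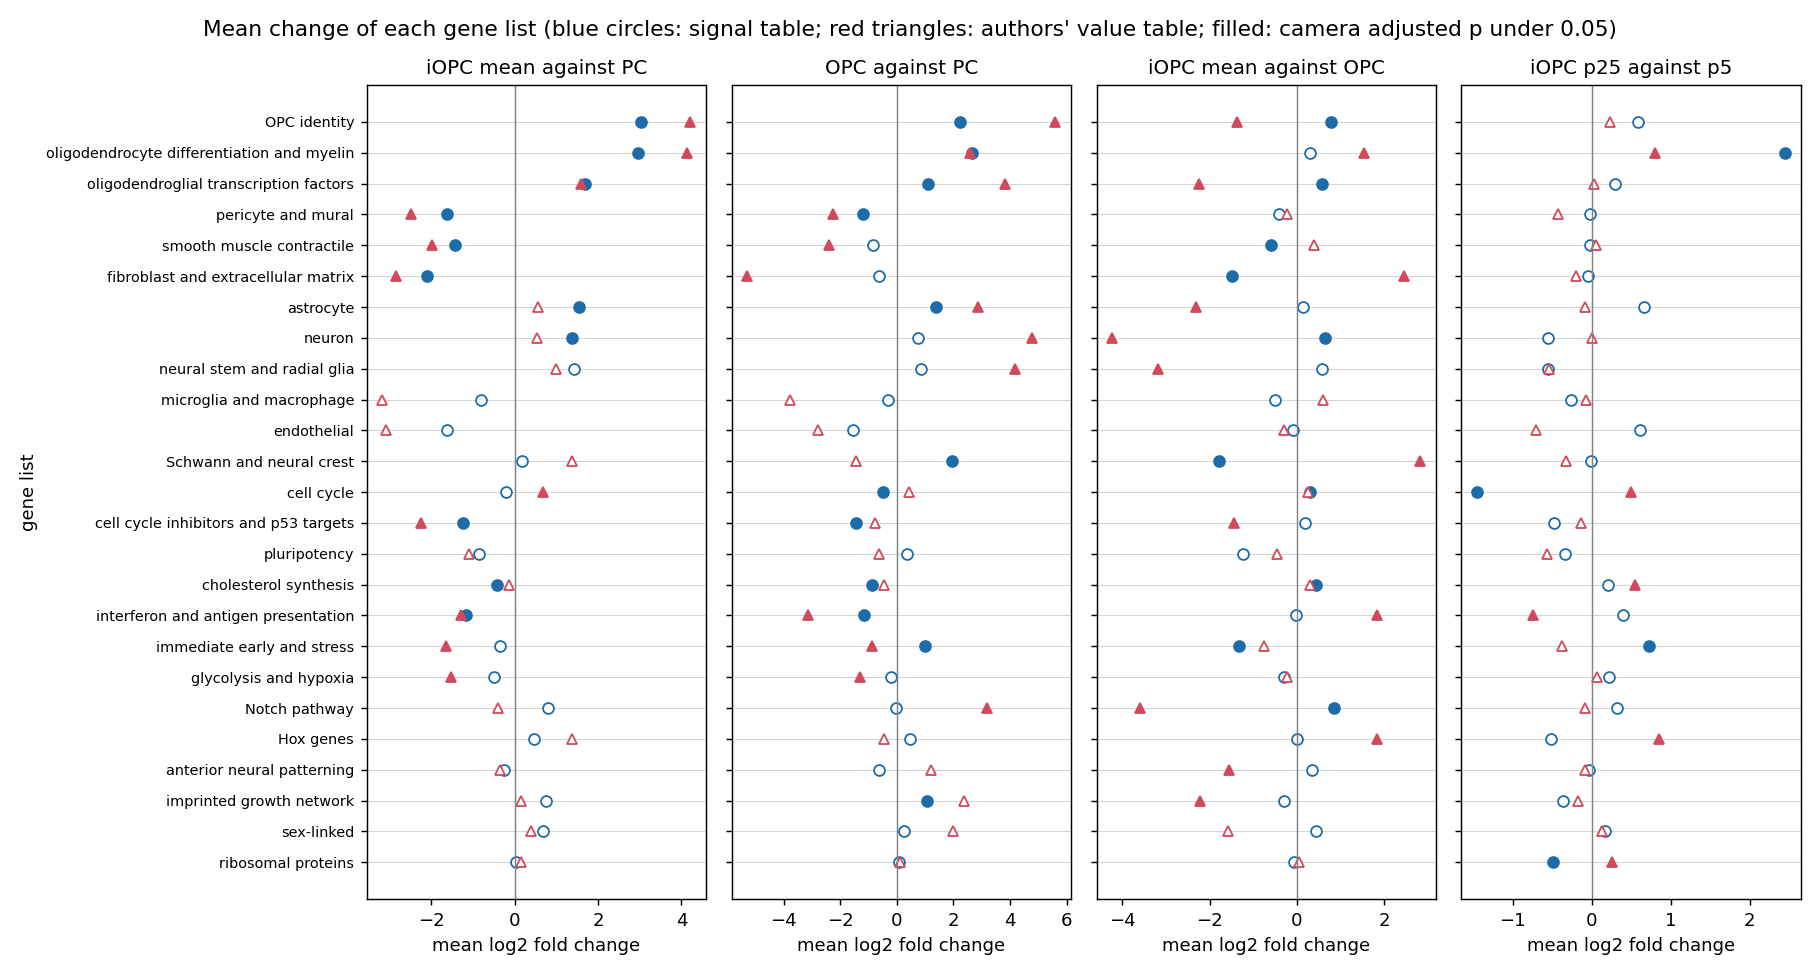
Mean log2 fold change of the tested members of each of 25 gene lists (vertical axis) in the 4 main comparisons (panels), from the signal table (blue circles) and the authors' value table (red triangles), filled where the camera adjusted p was under 0.05. Against PC the OPC identity, myelin and transcription factor lists lie to the right in both tables, while in iOPC against OPC the OPC identity list lies at 0.79 in one and at -1.38 in the other.

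Primary OPC, as headed in each table, also stood above pericytes in glial genes and below them in mural and interferon genes. Igfbp2 was higher by at least 177-fold and 9.42, Atp1b2 by at least 81.6-fold and 7.78 and Aldoc by 6.75 and 7.75. Chil1, a chitinase-like secreted protein, was higher by at least 96.2-fold and 4.53, Cldn11 by 7.71 and 5.83, and Col9a2, a chain of collagen IX, by at least 203-fold and 3.27. A pair of top rises of the signal table did not rise in the value table: Col2a1, the collagen of cartilage (at least 156-fold, against a value table change of 0.21 with adjusted p = 0.499), and Lum (at least 130-fold, against -1.88, a fall). Lower in OPC were Prl2c3 (at least 571-fold lower and -12.72), Prl2c4 (at least 458-fold lower and -12.24), Klra4 (at least 171-fold lower and -10.62), Lox (-6.98 and -10.00), Anxa3 (-8.10 and -5.44) and the surface glycoprotein Msln (at least 67.4-fold lower and -9.64). On the signal side Lox and Anxa3 were each detected on 1 of the 2 OPC arrays. Ccnd2, a cyclin of the G1 phase, fell in the signal table (-7.09) and changed by 0.41 in the value table (adjusted p = 0.449).

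Among the fixed markers, Pdgfra (2.05 and 3.49), Cspg4 (3.78 and 3.84), Olig1 (at least 38.6-fold higher and 12.03), Sox2 (at least 18.5-fold higher and 6.56) and Mbp (at least 14.6-fold higher and 3.17) were higher in OPC, and Pdgfrb (-3.37 and -6.41), Acta2 (-2.35 and -2.93) and Cdkn2a (at least 35.3-fold lower and -1.01) lower, in both tables. Olig2 was higher (0.41 in the signal table, where 1 of the 2 OPC arrays detected it, and 6.38 in the value table). Its call in the signal table ended without PC replicate 1 (adjusted p = 0.0609) and without background correction (adjusted p = 0.0653). Nkx2-2 was below background on the signal arrays of both groups (adjusted p = 0.879) and higher by 9.62 in the value table. Col1a1 was higher by 0.41 in the signal table, a call lost with median scaling (adjusted p = 0.0561), and changed by -7.22 in the value table. Gfap was at least 3.36-fold higher in the signal table and changed by 0.13 in the value table (adjusted p = 0.858).

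Among 23 tested OPC identity genes, 18 rose and 0 fell in the signal table (camera adjusted p = 1.26e-06), and 19 and 2 did so in the value table (camera adjusted p = 1.92e-07). OPC identity genes gave adjusted p = 0.055 with an estimated correlation in the value table. Scrg1 rose by at least 29.1-fold and 9.13 and Bcan by at least 18.6-fold and 10.29, while Matn4, a matrix protein, changed by 5.43 and -0.95. Of the oligodendrocyte differentiation and myelin genes, 17 of 23 tested members rose and 2 fell in the signal table (18 and 2 adjusted over the list alone, camera adjusted p = 1.26e-06), and 14 rose and 1 fell in the value table (camera adjusted p = 0.00123). Myelin genes gave adjusted p = 0.0729 with an estimated correlation in the value table. Ugt8a rose by at least 40.2-fold and 7.61, Gal3st1 by at least 22.9-fold and 7.27 and the phosphodiesterase Enpp6 by at least 24.4-fold and 2.36. The oligodendroglial transcription factors had 15 of 25 tested members higher and 1 lower in the signal table (camera adjusted p = 0.0026), and 19 higher and 0 lower in the value table (20 and 0 adjusted over the list alone, camera adjusted p = 2.03e-07). Transcription factors gave adjusted p = 0.0564 with an estimated correlation in the signal table. Among 20 tested astrocyte markers, 12 rose and 4 fell in the signal table (camera adjusted p = 0.0199), and 13 and 4 did so in the value table (14 and 4 adjusted over the list alone, camera adjusted p = 0.00237). Astrocyte markers gave adjusted p = 0.108 and 0.055 with an estimated correlation. Of the interferon and antigen presentation genes, 0 of 18 tested members rose and 15 fell in the signal table (camera adjusted p = 0.000132), and 0 rose and 15 fell in the value table (camera adjusted p = 3.14e-06). Interferon genes gave adjusted p = 0.0564 and 0.055 with an estimated correlation. Oasl2 (at least 9.58-fold lower and -6.15), Usp18 (at least 8.06-fold lower and -5.85) and Ifit3 (-2.07 and -5.34) were lower. The pericyte and mural genes had 3 of 18 tested members higher and 13 lower in the signal table (camera adjusted p = 0.0026), and 5 higher and 12 lower in the value table (camera adjusted p = 0.0133). Pericyte and mural genes gave adjusted p = 0.13 and 0.0725 with an estimated correlation. Nid1 (-5.15 and -6.36) and the transcription factor Foxd1 (at least 8.93-fold lower and -4.81) were lower, and Mcam (5.25 and 1.15) was higher.

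The tables parted on the other lists. Among 30 tested fibroblast and extracellular matrix genes, 10 rose and 17 fell in the signal table (camera adjusted p = 0.103), and 1 and 28 did so in the value table (1 and 29 adjusted over the list alone, camera adjusted p = 2.44e-14). Dcn, a matrix proteoglycan, changed by 4.16 and -6.13 and Fbln2 by -5.37 and -3.73. Of the smooth muscle contractile genes, 2 of 12 tested members rose and 7 fell in the signal table (camera adjusted p = 0.062), and 0 rose and 9 fell in the value table (camera adjusted p = 0.00011). Smooth muscle genes gave adjusted p = 0.055 with an estimated correlation in the value table. Tpm2 was lower (at least 26.7-fold lower and -7.90). The signal shift of this list passed with median scaling (adjusted p = 0.0317), with no detection filter (0.0183) and without either passage 25 array (0.0488 and 0.0492). The immediate early and stress genes had 11 of 16 tested members higher and 2 lower in the signal table (camera adjusted p = 0.0199), and 2 higher and 7 lower in the value table (camera adjusted p = 0.0446). Immediate early and stress genes gave adjusted p = 0.108 and 0.152 with an estimated correlation. Fos (3.89 and 0.33), Jun (2.06 and 0.84), Atf3 (at least 6.12-fold higher and -0.82) and Junb (2.05 and -2.42), transcription factors of the early response, were its largest signal changes, and Fos and Atf3 did not pass in the value table. Among 8 tested Schwann cell and neural crest markers, 6 rose and 1 fell in the signal table (camera adjusted p = 0.0118), and 1 and 4 did so in the value table (1 and 5 adjusted over the list alone, camera adjusted p = 0.0982). Schwann cell and neural crest markers gave adjusted p = 0.108 with an estimated correlation in the signal table. Egr2, a transcription factor of myelinating Schwann cells, changed by 4.87 and -0.67, the neurotrophin receptor Ngfr was higher in the signal table (at least 7.76-fold higher and 0.34) and Tfap2a, a neural crest transcription factor, changed by 2.83 and -4.55. In the signal table alone, cell cycle genes shifted down (1 higher and 19 lower of 28, camera adjusted p = 0.00172, and adjusted p = 0.0564 with an estimated correlation). Cell cycle inhibitors and p53 targets (4 higher and 13 lower of 18, 4 and 14 adjusted over the list alone, camera adjusted p = 0.00172, and adjusted p = 0.0564 with an estimated correlation) and cholesterol synthesis genes (0 higher and 13 lower of 18, camera adjusted p = 0.000459, and adjusted p = 0.13 with an estimated correlation) did so too, and imprinted growth genes shifted up (6 higher and 2 lower of 12, camera adjusted p = 0.0372, and adjusted p = 0.148 with an estimated correlation). In the value table alone, neuron markers (12 higher and 1 lower of 13, camera adjusted p = 9.01e-06, and adjusted p = 0.055 with an estimated correlation) and neural stem genes (9 higher and 1 lower of 11, camera adjusted p = 0.00123, and adjusted p = 0.055 with an estimated correlation) shifted up. Notch pathway genes were also higher there (10 higher and 2 lower of 15, camera adjusted p = 0.00276, and adjusted p = 0.055 with an estimated correlation), and glycolysis genes lower (1 higher and 11 lower of 19, camera adjusted p = 0.00579, and adjusted p = 0.055 with an estimated correlation). The signal mean of neuron markers, 0.73 with all arrays, was 1.19 without either array headed passage 15. In all, 12 and 13 lists passed, and 2 and 2 of these held with an estimated correlation.

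In this comparison 3423 genes were higher and 3211 lower in the signal table and 2993 and 2525 in the value table, of which 1145 and 1068, and 2112 and 1885, changed at least 2-fold. The tables shared 1837 rises and 1695 falls, and 641 genes were opposite, with r = 0.571 across genes. Independence would give 1048 and 829, but the PC columns match. Standard errors of the named genes ran from 0.07 to 0.17 and from 0.14 to 0.86 (2 arrays per group). The largest limma adjusted p among the named genes that passed was 0.00741 and 0.0447.

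Against primary OPC the direction of most iOPC changes called in both tables depended on the table. Genes that fell in both included the early response transcription factors Junb (-3.12 and -3.04), Egr2 (-4.02 and -2.97), Fos (-2.58 and -2.23) and Egr1 (-1.82 and -4.04), together with Lgals3, a galactose-binding lectin (-4.22 and -1.99), Pdgfra (-0.29 and -1.49) and Sox2 (-0.24 and -1.04). The Sox2 call in the signal table ended without OPC replicate 1 (adjusted p = 0.154). At passage 15 alone the signal table called Pdgfra (1.44) and Sox2 (0.75) higher than OPC, and the Pdgfra fall came from passage 25 (-2.51), with passage 5 not passing (0.19, adjusted p = 0.0856). Higher in both were S100a16, a calcium-binding protein (1.43 and 2.27), and the membrane protein Tmem108 (1.14 and 2.60). Opposite calls were made for Olig1 (2.06 and -2.32), Olig2 (0.93 and -3.62), Nkx2-2 (at least 3.97-fold higher and -3.52), Sox8 (2.82 and -3.52), Bcas1 (3.02 and -1.03), Col1a1 (-1.37 and 5.12) and Cdkn2a (at least 2.16-fold higher and -7.23). With both arrays headed passage 15 left out, the signal table called Col1a1 up (0.45, adjusted p = 0.00172), as the value table does, and Cdkn2a was below background on every remaining array of both sides. Olig2 was detected on no array of passages 5 and 25, and its signal rise rests on passage 15: without these arrays it did not meet the detection filter. Cntn1, an adhesion protein of neural cells (3.96 and -1.44), Acsbg1, a lipid enzyme of brain (2.78 and -7.66), the channel genes Cacng4 (at least 4.89-fold higher and -2.62) and Chrna4 (2.73 and -3.29) and the kinase Prkcq (at least 4.34-fold higher and -0.66) rose in the signal table and fell in the value table. Dcn (-4.77 and 3.99), the chemokine Cxcl1 (-4.28 and 1.89), the transcription factor Klf4 (-4.23 and 2.40), Lum (-3.90 and 5.64), the matrix protein Tgfbi (-3.77 and 5.32) and the matrix protease Mmp2 (-3.65 and 10.00) did the reverse. Col2a1 fell in the signal table (-3.82) and changed by -0.15 in the value table (adjusted p = 0.561). Mbp (signal change -0.17, adjusted p = 0.144) rose in the value table (3.48), and without both arrays headed passage 15 the signal table also called it up (1.18, adjusted p = 1.75e-05). Cspg4 passed in neither (adjusted p = 0.423 and 0.558), though upward in the signal table without these arrays (0.25, adjusted p = 0.0312). Pdgfrb (at least 1.12-fold lower), Acta2 (-0.49) and Gfap (-1.04) were lower in the signal table alone, though at passage 25 Acta2 (0.45, adjusted p = 0.00109) and Gfap (0.73, adjusted p = 0.000187) were called higher.

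No gene list shifted the same way in both tables, and 6 were called in opposite directions, of which 4 were up in the signal table and down in the value table. This rested in part on the arrays headed passage 15. Without both of them the signal table called myelin (mean log2 change 0.98, adjusted p = 3.85e-08) and interferon genes (0.49, adjusted p = 0.00281) up. It called imprinted growth genes (-0.81, adjusted p = 0.00281) and neuron markers (-0.45, adjusted p = 0.034) down. These are the directions of the value table, and transcription factors (adjusted p = 0.884) and Notch genes (adjusted p = 0.355) no longer passed. With all arrays, for OPC identity genes, 13 rose and 4 fell of 23 in the signal table (camera adjusted p = 0.00193) and 4 and 13 in the value table (camera adjusted p = 0.024), with adjusted p = 0.0561 and 0.271 with an estimated correlation. For oligodendroglial transcription factors, 16 rose and 6 fell of 25 in the signal table (camera adjusted p = 0.00977) and 3 and 20 in the value table (camera adjusted p = 1.63e-05), with adjusted p = 0.0657 and 0.0318 with an estimated correlation. In neuron markers, 9 rose and 1 fell of 13 in the signal table (9 and 2 adjusted over the list alone, camera adjusted p = 0.00438) and 1 and 12 in the value table (camera adjusted p = 1.94e-06), with adjusted p = 0.0651 and 0.0318 with an estimated correlation. In Notch pathway genes, 11 rose and 3 fell of 15 in the signal table (camera adjusted p = 0.00438) and 1 and 13 in the value table (camera adjusted p = 9.9e-06), with adjusted p = 0.0651 and 0.0318 with an estimated correlation. The other 2 were down in the signal table and up in the value table. For extracellular matrix genes, 1 rose and 23 fell of 30 in the signal table (1 and 24 adjusted over the list alone, camera adjusted p = 1.67e-11) and 19 and 6 in the value table (camera adjusted p = 0.000157), with adjusted p = 0.0412 and 0.0318 with an estimated correlation. In Schwann cell and neural crest markers, 1 rose and 7 fell of 8 in the signal table (camera adjusted p = 0.000317) and 7 and 1 in the value table (camera adjusted p = 0.00681), with adjusted p = 0.0561 and 0.0808 with an estimated correlation. In the Notch list the target genes Hey1 (2.62 and -2.93), Hes5 (at least 2.56-fold higher and -7.26) and Nrarp (at least 3.94-fold higher and -6.71) and the ligand Dner (at least 5.06-fold higher and -9.04) moved in opposite directions. So did Matn4 (-2.14 and 6.06), Tfap2b, a neural crest transcription factor like Tfap2a (-3.33 and 8.08), Tfap2a itself (-2.42 and 7.40) and Ngfr (-2.69 and 2.40). The signal calls of Dner (0.089, adjusted p = 0.761) and Matn4 (-0.20, adjusted p = 0.0982) ended without both arrays headed passage 15, and Hes5 then did not meet the detection filter.

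The other lists passed in one table. Immediate early and stress genes fell in the signal table (1 higher and 13 lower of 16, camera adjusted p = 9.49e-07), and did not pass in the value table (3 higher and 6 lower of 16, camera adjusted p = 0.272), where Atf3 changed by 0.26 (adjusted p = 0.503). Dusp1, a phosphatase of the early response, moved apart (-2.63 and 0.48). In the signal table alone, cell cycle genes (17 higher and 0 lower of 28, 18 and 0 adjusted over the list alone, camera adjusted p = 0.00212, and adjusted p = 0.0561 with an estimated correlation) and cholesterol synthesis genes (14 higher and 1 lower of 18, camera adjusted p = 0.00193, and adjusted p = 0.152 with an estimated correlation) shifted up and smooth muscle genes down (1 higher and 7 lower of 12, camera adjusted p = 0.00442, and adjusted p = 0.0651 with an estimated correlation). In the value table alone, myelin genes (14 higher and 3 lower of 23, camera adjusted p = 0.00272, and adjusted p = 0.107 with an estimated correlation) and interferon genes (14 higher and 0 lower of 18, 15 and 0 adjusted over the list alone, camera adjusted p = 7.27e-05, and adjusted p = 0.077 with an estimated correlation) shifted up, and Hox genes too (4 higher and 0 lower of 5, camera adjusted p = 0.024, and adjusted p = 0.107 with an estimated correlation). Astrocyte markers (3 higher and 14 lower of 20, camera adjusted p = 0.000305) and neural stem genes (0 higher and 10 lower of 11, camera adjusted p = 1.63e-05) shifted down there. The same held for cell cycle inhibitors and p53 targets (2 higher and 9 lower of 18, camera adjusted p = 0.00781, and adjusted p = 0.107 with an estimated correlation), anterior neural patterning genes (1 higher and 7 lower of 11, 2 and 7 adjusted over the list alone, camera adjusted p = 0.0232, and adjusted p = 0.107 with an estimated correlation) and imprinted growth genes (3 higher and 8 lower of 12, camera adjusted p = 0.0263, and adjusted p = 0.158 with an estimated correlation). Without either single array headed passage 15 the signal calls of the transcription factors (camera adjusted p = 0.0688 and 0.0645), neuron markers (0.231 and 0.233) and Notch genes (0.0764 and 0.0725) ended. The mean log2 change stayed near that of all arrays for transcription factors (0.55 and 0.54, with all 0.58) and Notch genes (0.71 and 0.71, with all 0.85), and fell for neuron markers (0.33 and 0.33, with all 0.65). Cell cycle (-0.0097, adjusted p = 0.879) and smooth muscle signal calls (-0.36 after -0.59, adjusted p = 0.099) ended without both arrays headed passage 15. In all, 10 and 14 lists passed, and 2 and 6 of these held with an estimated correlation.

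The signal table called 3050 genes higher and 2508 lower in iOPC than in OPC (2382 and 2736 with median scaling), and the value table called 2773 and 2635. Both called 522 higher, 426 lower and 2540 in opposite directions (1533 if independent), with r = -0.501 across genes. For passages 5, 15 and 25 r was -0.083, -0.685 and 0.047. Signal passage 15 matches value columns headed OPC, which builds in opposition. At least 2-fold calls were 331 and 495, and 1562 and 1563. Without both arrays headed passage 15 the signal table gave 4479 calls in place of 5558. Standard errors of the named genes ran from 0.06 to 0.20 and from 0.13 to 0.71 (2 arrays per group). The largest limma adjusted p among the named genes that passed was 0.0129 and 0.0368.

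Between passages 5 and 25, myelin genes rose in both tables. Mag, an adhesion protein of myelin, rose by 7.84 and 2.49 (detected on 1 of the 2 signal arrays of passage 5), Bcas1 by 4.04 and 3.53, Enpp6 by 3.83 and 3.27, Mbp by 1.72 and 4.93 and Fxyd6, a regulator of the sodium pump, by 4.55 and 4.82. Kcna1, a potassium channel (at least 122-fold higher and 2.34), and Ptgds, a prostaglandin synthase of glia (5.75 and 1.91), rose in both tables. The rises of Mog, a protein of the outer myelin surface (at least 84.3-fold), Hhatl (at least 94-fold), Tubb4a, a tubulin of myelinating oligodendrocytes (6.61), and Slc16a8, a lactate transporter (at least 26.3-fold), passed in the signal table alone (value table limma adjusted p = 0.202, 0.802, 0.227 and 0.529). Of the oligodendrocyte differentiation and myelin genes, 20 of 23 tested members rose and 1 fell in the signal table (camera adjusted p = 2.29e-11), and 8 rose and 1 fell in the value table (9 and 1 adjusted over the list alone, camera adjusted p = 0.000197). Myelin genes gave adjusted p = 0.146 with an estimated correlation in the value table. Mal, a myelin proteolipid, rose by 4.39 in the signal table and changed by -0.03 in the value table (adjusted p = 0.942). Lower at passage 25 in both were Wfdc18, a secreted protease inhibitor-like protein (at least 34.6-fold lower and -1.91), the integrin Itgb5 (at least 6.99-fold lower and -3.14), the scavenger receptor Scara3 (-2.42 and -4.19) and Eva1b (-3.22 and -5.79), the last detected on 1 of the 2 signal arrays of passage 25.

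Cell cycle and ribosomal genes moved apart between the tables. The cell cycle genes had 0 of 28 tested members higher and 27 lower in the signal table (camera adjusted p = 2.14e-12), and 7 higher and 0 lower in the value table (10 and 1 adjusted over the list alone, camera adjusted p = 1.25e-05). Cell cycle genes gave adjusted p = 0.0595 with an estimated correlation in the value table. Kif11, a motor of the mitotic spindle, changed by -2.47 and 0.27, Birc5, a mitotic survivin protein, by -1.98 and 0.30 and Cdk1, the mitotic kinase, by -1.85 and 0.62, of which none passed in the value table, and Rrm2, which makes deoxynucleotides, by -2.09 and 0.57. Among 19 tested ribosomal protein genes, 0 rose and 15 fell in the signal table (camera adjusted p = 0.000892), and 1 and 0 did so in the value table (0 and 0 adjusted over the list alone, camera adjusted p = 0.0315). Ribosomal protein genes gave adjusted p = 0.224 and 0.408 with an estimated correlation. Rpl4 changed by -0.99 and 0.76, and Rps6 (-0.89), Rps16 (-0.83) and Rpl19 (-0.79) fell in the signal table alone. The mean log2 level of this list in the value table was 12.30 in the first column of passage 5, which stood apart from its replicate, 12.53 in the second, and 12.67 and 12.69 at passage 25. For cell cycle genes it was 8.51, 8.70, 9.10 and 9.12. Immediate early and stress genes rose in the signal table (11 higher and 1 lower of 16, camera adjusted p = 0.0035, and adjusted p = 0.121 with an estimated correlation) and not in the value table (camera adjusted p = 0.477). Fosb (2.72), Ier2 (1.65) and Fos (1.61) rose in the signal table, and Egr1 in both (1.52 and 2.26). Passing in the value table alone, cholesterol synthesis genes (3 higher and 0 lower of 18, 7 and 1 adjusted over the list alone, camera adjusted p = 0.000505, and adjusted p = 0.129 with an estimated correlation) and Hox genes (3 higher and 0 lower of 5, camera adjusted p = 0.0148, and adjusted p = 0.181 with an estimated correlation) shifted up. Interferon genes shifted down there (0 higher and 5 lower of 18, 0 and 9 adjusted over the list alone, camera adjusted p = 0.00165, and adjusted p = 0.196 with an estimated correlation). In all, 4 and 6 lists passed, and 2 and 0 of these held with an estimated correlation.

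Of the fixed markers, Pdgfra fell in the signal table (-2.70) and changed by -0.20 in the value table (adjusted p = 0.617). Col1a1 rose in both (1.00 and 2.16). Acta2 was called in opposite directions (1.89 and -1.30). Gfap (2.39), Olig1 (0.94) and Nkx2-2 (at least 1.3-fold higher) rose and Cspg4 fell (-0.47) in the signal table alone. Sox2 passed in neither table (adjusted p = 0.571 and 0.895), and Olig2, Pdgfrb and Cdkn2a were below background on the signal arrays of both passages (value table adjusted p = 0.215, 0.813 and 0.633). The largest signal falls, in the secreted proteins Dcpp3 (at least 47.1-fold lower and 1.58), Dcpp2 (-5.62 and 0.87) and Dcpp1 (-4.63 and 0.73), near-identical copies whose probes are uncertain, Cytl1 (-5.25 and 1.06), the casein Csn3 (at least 19.5-fold lower and -0.47), the transcription factor Meox1 (at least 22.8-fold lower and -0.46) and the signalling protein Bmp7 (-4.53 and 0.38), were not called down in the value table.

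Passage 25 against passage 5 gave 2584 higher and 2876 lower genes in the signal table but 328 and 543 in the value table, with 108 and 172 shared, 319 opposite and r = -0.0185 across genes. At least 2-fold calls were 728 and 633, and 182 and 371. The signal table's split depended on the scaling: with median scaling, which moved the median gene by -0.18, it was 1630 higher and 4041 lower. In the value table single arrays decided the count. It was 2622 without passage 5 replicate 2, 486 without either PC array, 445 without either OPC array, and 291 and 252 without passage 25 replicates 1 and 2. Passage 15 against 5 gave 3187 higher and 2952 lower in the signal table and 357 and 652 in the value table. Between passages 15 and 25 there were 3272 higher and 3746 lower in the signal table and 11 and 1 in the value table. Differences among the 3 passages (limma F test) passed in 7957 genes of the signal table and in 874 of the value table. Without the same arrays the value table's F test count rose and fell, and it fell without either passage 15 array. It also held that limit without passage 5 replicate 1. Standard errors of the named genes ran from 0.07 to 0.24 and from 0.14 to 0.86 (2 arrays per group). The largest limma adjusted p among the named genes that passed was 0.00142 and 0.0465.

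Each passage was also set against PC and OPC. Against PC, passage 5 gave 3496 higher and 3004 lower in the signal table and 2953 and 2354 in the value table. For passage 15 there were 3939 higher and 3297 lower in the signal table and 2840 and 2397 in the value table, and for passage 25 3597 higher and 3486 lower in the signal table and 2842 and 2377 in the value table. Against OPC, passage 5 gave 2064 higher and 1833 lower in the signal table and 2518 and 2281 in the value table. Passage 15 had 3541 higher and 3023 lower in the signal table and 2399 and 2324 in the value table, and passage 25 2617 higher and 2825 lower in the signal table and 2420 and 2293 in the value table. With median scaling the signal split of passage 25 became 2580 higher and 4485 lower against PC, 1539 and 4099 against OPC, and 2385 and 4921 against passage 15.

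On a line from the PC mean (0) to the OPC mean (1) over all 9778 genes, the iOPC arrays of the signal table lay at 0.946 ± 0.000857 (SD, n = 2) for passage 5, 0.769 ± 0.000182 for passage 15 and 0.985 ± 0.00465 for passage 25. In the value table they lay at 0.540 ± 0.00534, 0.579 ± 0.000318 and 0.581 ± 0.000559. With 2 arrays on each side an exact permutation test cannot give a p below 0.333, and no other test of these positions was made. Simulated groups with no change from PC lay at 0.00375 and 0.0101. Of the genes called between OPC and PC, 81.4% (5400 of 6634) in the signal table and 63.9% (3526 of 5518) in the value table were called the same way between iOPC and PC, and 308 and 462 the opposite way. These were 2821 up and 2579 down, and 1901 up and 1625 down, where independent lists would share 1447 and 1094, and 987 and 676. Both comparisons use the same PC arrays, which are too few to split. In the simulations every group, OPC included, was drawn from the PC mean, so their 0 shared calls followed from the setting and give no comparison. Their correlations of 0.616 and 0.615 are those of noise through the shared arrays. They set no level for the observed correlations of 0.874 and 0.676, since OPC differed from PC in many genes. The covariance of the changes was 1.31 against a simulated 0.00633 in the signal table and 2.92 against 0.0507 in the value table, and part of the excess may come from the shared controls.

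**Figure D4:**
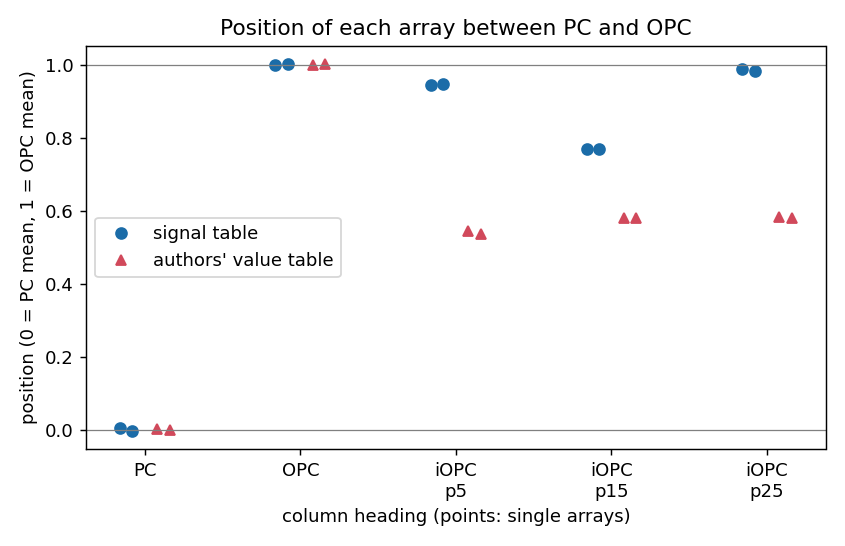
Position of every array (points) on the line from the PC mean (0) to the OPC mean (1), by column heading, in the signal table (blue circles) and the authors' value table (red triangles). The iOPC arrays lie at 0.946, 0.769 and 0.985 for passages 5, 15 and 25 in the first and at 0.540, 0.579 and 0.581 in the second. The OPC end of the line and passage 15 rest on headings in doubt.

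Genes at least 2-fold higher in iOPC than in both PC and OPC numbered 235, and at least 2-fold lower than in both 223, in the signal table, and 610 and 505 in the value table. The signal table's total of 458 fell to 161 without background correction, 231 with normexp and 300 without both arrays headed passage 15. The tables shared 10 of the first and 20 of the second, where independent lists would share 14.7 and 11.5. The shared higher genes were Mog (1.88 and 8.09), Tubb4a (1.20 and 2.36), Lgi3 (1.24 and 3.19), Matn1 (1.35 and 2.36), Ninj2 (1.24 and 1.10), Hdhd3 (1.41 and 1.28), Tmem108 (1.14 and 2.60), Slc35g1 (1.12 and 1.28), Kcnj12 (1.10 and 1.05) and Lims2 (1.10 and 2.22), each with the smaller of its log2 changes against PC and OPC. The shared lower genes included Lgals3 (-4.22 and -1.99), the inhibitors of differentiation Id1 (-2.11 and -1.20) and Id3 (-1.43 and -2.79), the chemokine Ccl7 (-1.98 and -1.10), and the matrix-associated Nid1 (-1.71 and -3.19), Fstl1 (-1.59 and -2.50) and Ccdc80 (-1.79 and -1.51). The signal fall of Ccl7 against OPC ended without both arrays headed passage 15 (-0.14, adjusted p = 0.107). Single passages went against the mean: in the signal table Tubb4a (-2.12) and Lims2 (-0.36) were lower than OPC at passage 5 and Ninj2 at passage 15 (at least 1.71-fold), and Mog was below background at both. So was Lgi3 at passage 5 and in OPC, and its place rests on a fitted change. These genes were named after their values were seen.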

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

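The tests of the mismatch between the tables, and those of low signals and of probes that fell together in the first passage 5 column, were chosen after the result was seen, while the tests on the median change of a gene's other probes were written before.

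Pdgfra differed between passages under the comparison with PC: in the signal table its level at passage 25 lay -2.70 log2 units from passage 5 (limma adjusted p = 2.46e-09), so that it stood above PC at passage 5 and below PC at passage 25. The value table showed -0.20 (adjusted p = 0.617). Col1a1 differed likewise, with passage 15, where it was below background, at least 23.5-fold lower than passage 5 in the signal table. The fitted change was -4.96 (limma adjusted p = 1.54e-11), against 2.34 in the value table (adjusted p = 0.00445). Both differences lie between columns whose headings are in doubt. Among 1719 probes with no gene symbol, which no comparison used, 26 were detected on all 6 arrays headed iOPC and on neither PC array, and 33 the other way round, and 859 of these probes passed the detection filter.

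The like-named columns of the tables held different profiles. A normalization of the same arrays would leave every like-named pair of columns about as close as the PC columns are, whose lowest Pearson r was 0.957. Among the other headings the highest r of a like-named pair was 0.887, which argues against normalization as the whole cause. For the headings OPC and iOPC passage 15 exchanged in one table, one side matched: the change from PC in the value columns headed OPC correlated at 0.965 across genes with that of the signal columns headed iOPC passage 15, which is consistent with the same cells under both headings. The other side did not, with 0.702 between the value columns headed iOPC passage 15 and the signal columns headed OPC, so a plain exchange does not account for the remaining columns. Y-linked RNA argues against a change with passage in cells grown from pericytes of the PC arrays. Its 3 genes, below background there, rose by a median of at least 2.52 log2 units on signal arrays headed passage 15. If all passages came from those pericytes, this argues against that signal heading, but not the value table's. Pericytes from other mice remain open.

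The value table's column of passage 5 replicate 1 stood apart from replicate 2, with 1447 genes over 2-fold apart against 425 at passage 15 and 474 at passage 25. In 560 cases where 1 probe of a gene was at least 4-fold lower in that column (median -2.94), the gene's other probes changed by a median of -0.26 (quartiles -1.26 and 0.14). Another expression state of that culture would lower all probes of a gene by about the same, so this argues against it as the whole cause. The median of -0.26 met the prediction written before for a loss of signal at single probes. A condition on shuffles was added after the result was seen. With it the median does not decide, since the other probes went both ways. In 30.2% of cases they were at least 2-fold lower too, against at most 18.9% in 20 shuffles of the changes among probes, which argues against such a loss as the whole cause. Eef2 fell at each of its 3 probes (-6.55, -6.10 and -5.92). Noise of low signals is argued against by the brightest genes (upper quartile), of which 4.09% were over 2-fold apart, against 0.0409% at passage 15 and 0% at passage 25. What lowered these values is open, a mixture included, and no biological explanation beyond the culture's state was tested.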

How the results depend on the processing

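Leaving out the arrays headed iOPC passage 15 or OPC and leaving out arrays of the value table were chosen after the data were seen, and the other alternatives were planned.

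Named genes moved little outside the value table. Checks of named genes with other background corrections, scaling, filters, variance models and arrays left out numbered 4567, of which 4551 kept their direction and their side of the threshold. Counts of calls stayed within 1.5 times of the reported ones under every alternative set before the data were seen, other than the value table and the 2-fold threshold, with these exceptions. The 37 list calls of the main contrasts in the signal table became 13 with an estimated correlation. Genes unlike both PC and OPC were 458, and 161 without background correction and 231 with normexp. The mean position of 0.9 became 0.878 without background correction, 0.887 with normexp and 0.897 over all probes, and lay between 0.882 and 0.902 with single arrays left out. With at least 2-fold changes the calls were 2213 (OPC against PC), 2452 (iOPC against PC) and 826 (iOPC against OPC). By passage they were 2226, 3162 and 2832 for passages 5, 15 and 25 against PC and 442, 2343 and 1272 against OPC. Between passages they were 2158 (15 against 5), 1361 (25 against 5) and 2757 (25 against 15). Among lists that did not pass in the signal table, besides those given with a comparison, some passed under alternatives. Myelin genes in iOPC against OPC, up in the value table, passed upward without background correction (adjusted p = 0.00355), with normexp (0.00914) and with no detection filter (0.0269). Notch pathway genes in iOPC against PC passed upward under these (0.0333, 0.0368 and 0.0191) and with median scaling (0.0161), and so did astrocyte markers in passage 25 against 5 (0.0375, 0.0361, 0.0316 and 0.00304). Glycolysis and hypoxia genes in iOPC against OPC passed downward under the first 3 (0.0369, 0.0403 and 0.0181) and with trend and robust variance (0.0397). Median scaling also passed OPC identity in passage 25 against 5 (0.00927) and neural stem (0.02) and anterior patterning genes (0.0184) in iOPC against OPC, all upward. With no filter, anterior patterning (0.0439) and cell cycle inhibitors (0.0181) passed upward there, and the latter downward in passage 25 against 5 (0.0152).

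Single arrays ended 2 gene calls, both given with the comparison, made 1 (Myc in iOPC against PC without passage 25 replicate 1, adjusted p = 0.00739) and moved no count of the signal table by over 1.5 times. Of list calls they ended 8 and made 12. Imprinted genes in OPC against PC did not pass without PC replicate 2 (1.01 after 1.05, adjusted p = 0.0823). A lone array left in a group was taken to vary like the others.

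The replicate number as a block gave 6612 calls for OPC against PC, 7432 for iOPC against PC, 5536 for iOPC against OPC, 5423 for passage 25 against 5 and 37 list calls, and changed no named gene or list call. Arrays with the same number did not deviate together: 1 of 10 pairs of groups correlated over 0.1 in the signal table and 0 in the value table. A slide as a block was not run, since no slide is given.

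The value table changed directions, and the counts between passages, most. Calls became 1009 for passage 15 against 5, 871 for 25 against 5, 12 for 25 against 15, 874 for the F test (2807 at an unadjusted p under 0.05), 3526 for genes shared by the comparisons with PC and 1115 for genes unlike both, and the mean position 0.567. Within that table the count for passage 25 against 5 ran from 252 (without passage 25 replicate 2) to 2622 (without passage 5 replicate 2), the F test from 427 (without OPC replicate 1) to 2686 (without passage 5 replicate 2) and the position from 0.564 to 0.572. Of the named genes 61 reversed and 17 no longer passed, and of 100 list results 22 reversed, 9 no longer passed and 11 now did. Reversed here means another sign, whether or not the value passed. Called in opposite directions by both tables were 6 named genes and 1 list in OPC against PC, 1 and 0 in iOPC against PC, 27 and 6 in iOPC against OPC, and 4 and 2 in passage 25 against 5. As mean log2 change the reversed lists were, in OPC against PC, Schwann and neural crest -1.45, cell cycle 0.41, immediate early and stress -0.89 and Notch pathway 3.199. In iOPC against PC reversed lists were cell cycle 0.68. In iOPC against OPC reversed lists were OPC identity -1.38, oligodendroglial transcription factors -2.23, smooth muscle contractile 0.40, fibroblast and extracellular matrix 2.45, astrocyte -2.31, neuron -4.24, neural stem and radial glia -3.19, Schwann and neural crest 2.83, cell cycle inhibitors and p53 targets -1.45, interferon and antigen presentation 1.83, Notch pathway -3.60 and anterior neural patterning -1.56. In passage 25 against 5 reversed lists were cell cycle 0.50, interferon and antigen presentation -0.74, immediate early and stress -0.37, Hox genes 0.85 and ribosomal proteins 0.26. Reversed genes were, in OPC against PC, Atf3 -0.82, Ccnd2 0.41, Col1a1 -7.22, Dcn -6.13, Egr2 -0.67, Junb -2.42, Lum -1.88, Matn4 -0.95, Nkx2-2 9.62 and Tfap2a -4.55. For iOPC against PC they were Cldn11 -2.20. For iOPC against OPC they were Acsbg1 -7.66, Atf3 0.26, Bcas1 -1.03, Cacng4 -2.62, Cdkn2a -7.23, Chrna4 -3.29, Cntn1 -1.44, Col1a1 5.12, Cxcl1 1.89, Dcn 3.99, Dner -9.04, Dusp1 0.48, Gfap 0.16, Hes5 -7.26, Hey1 -2.93, Klf4 2.40, Lum 5.64, Matn4 6.06, Mbp 3.48, Mmp2 10.00, Ngfr 2.40, Nkx2-2 -3.52, Nrarp -6.71, Olig1 -2.32, Olig2 -3.62, Prkcq -0.66, Sox8 -3.52, Tfap2a 7.40, Tfap2b 8.08 and Tgfbi 5.32. For passage 25 against 5 they were Acta2 -1.30, Birc5 0.30, Bmp7 0.38, Cdk1 0.62, Cspg4 0.92, Cytl1 1.06, Dcpp1 0.73, Dcpp2 0.87, Dcpp3 1.58, Fosb -0.36, Gfap -0.21, Kif11 0.27, Mal -0.027, Olig1 -0.34, Rpl19 0.037, Rpl4 0.76, Rps16 0.14, Rps6 0.32, Rrm2 0.57 and Slc16a8 -0.52. The cause is weighed with the mismatch of the tables.

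Without both arrays headed passage 15, the signal change reversed in iOPC against PC for Col1a1 0.86. It did so in iOPC against OPC for Cdkn2a -0.091, Col1a1 0.45, Cspg4 0.25 and Mbp 1.18. Cdkn2a was below background on all arrays left on both sides, so its sign gives no direction. Olig2, En2 and Hes5 did not meet the detection filter then and have no value. Lists that reversed in iOPC against OPC were neuron -0.45, cell cycle -0.0097 and interferon and antigen presentation 0.49. Of these lists neuron (adjusted p = 0.034) and interferon (0.00281) passed. In iOPC against OPC pericyte and mural genes now passed downward (-0.50, 0.0186). Other list calls made or ended are given with the comparisons. Igf2 in iOPC against PC and Ccl7, Dner and Matn4 in iOPC against OPC no longer passed, and Myc in iOPC against PC did (adjusted p = 0.0103). Genes unlike both became 300 and the position 0.965. Without both arrays headed OPC, run for only these counts, iOPC against PC gave 7426 and passage 25 against 5 gave 5388. Signal over background limits genes near it: 45.7% to 49.2% of probes were detected, and for a gene undetected on one side the signal table gives only an at-least fold.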

Other observations

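All genes of this part were named after their values were seen. Among genes that pattern the brain, the forebrain homeobox genes Dlx1 (at least 20.9-fold lower and -5.21) and Dlx2 (at least 9.37-fold lower and -4.17) were lower in iOPC than in PC in both tables, and the midbrain gene En2 (at least 1.86-fold higher and 6.67) and the forebrain and midbrain gene Otx1 (at least 2.06-fold higher and 4.04) higher, the signal rise of En2 resting on the arrays headed passage 15, while the list as a whole did not pass (camera adjusted p = 0.617 and 0.232). In the Notch list the receptor Notch1 (2.23 and 1.94), the ligands Dll1 (at least 1.85-fold higher and 3.58) and Jag1 (0.73 and 1.24) and the target Hey1 (at least 5.92-fold higher and 4.80) were higher, and the mural receptor Notch3 (-1.80 and -5.03), the endothelial receptor Notch4 (-2.41 and -3.01) and the target Hes1 (-0.81 and -2.30) lower, in both tables. The list did not pass (camera adjusted p = 0.0697 and 0.595). Of neural progenitor genes, the fatty acid binding protein Fabp7 (at least 14.5-fold higher and 6.06) and the endothelin receptor Ednrb (at least 13.9-fold higher and 4.58) were higher and the growth factor receptor Egfr (-1.85 and -5.97) lower.

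Of 8 tested endothelial genes, 3 were higher and 4 lower in iOPC in the signal table, and 2 and 5 in the value table. Lower in both were the co-receptor Eng (at least 27-fold lower and -4.70), the surface sialoprotein Emcn (at least 23.1-fold lower and -7.55), the growth factor receptor Flt1 (-3.86 and -9.40) and the surface antigen Ly6c1 (at least 6.29-fold lower and -5.24). Vwf, a clotting protein of endothelium, was higher (at least 1.96-fold higher and 2.10), and the list did not pass (camera adjusted p = 0.343 and 0.0573). The imprinted genes Mest (at least 10.8-fold higher and 5.83), Snrpn (1.47 and 1.51) and Grb10 (0.98 and 6.17) were higher in both tables, and the growth factor Igf2 (-0.65 and -3.09) and Peg10 (-0.65 and -3.87) lower. These are means over passages, and in the signal table single passages were called the other way for Hes1 (passage 5, 0.48), Egfr and Peg10 (passage 15, 1.18 and 0.91), and Grb10 and Igf2 (passage 25, -0.35 and 1.06). Without both arrays headed passage 15 Igf2 did not pass (-0.18, adjusted p = 0.145). Of pluripotency genes, Klf4, one of the factors used in reprogramming, was lower (-3.95 and -3.81), and Myc passed in neither table (adjusted p = 0.0627 and 0.469).

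Among the iOPC columns of the value table, that of passage 5 replicate 1 stood alone. There, 52 genes lay at least 8-fold lower than in each of the other 5 iOPC columns, and 0 genes did so in any of the other iOPC columns. Eef2, an elongation factor of protein synthesis, had a value of 3.39 there and 9.94 in replicate 2.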
